A study of Rattus norvegicus with 2 samples.

How the data were processed

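Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on myocardium of male Wistar rats with abdominal aortic constriction. In this surgery a wire is tied to the aorta above the renal arteries and narrows it, which loads the heart with pressure. The labels list 2 samples of this model, a ChIP library and its input library, both with replicate number 3. They name the antibody by vendor and catalogue number only. Its target was taken here to be the lactylation of lysine 18 of histone H3 (H3K18la), which the series title names. How many animals gave the chromatin, and whether any had vagal stimulation, is not stated in the labels of these samples.

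The analysis started from the deposited peak list of the ChIP library and its annotation. Per the submitters' processing notes, FastQC, Trim Galore, Bowtie2, SAMtools, MACS2, deepTools and HOMER were used with the rat build rn6, and their versions and order were not given in the sources used here. Peak names carry a single sample name, per the file headers and names, so peaks were taken here as called on 1 library. A name alone cannot exclude a call on pooled samples. A path in the annotation's header names a call at q 0.05, and the largest q in the list was 0.0493. Whether the input library was the background of the call was not given in the sources used here.

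Each peak's fold enrichment is a ratio to the caller's local background, as the authors deposited it. The deposited p and q are given as −log10 values, per the file headers. The deposited score equals 10 times −log10 q cut to a whole number in all 28706 peaks, and the annotation by the authors copies that score. Fold enrichment and q are the authors' own values per peak and were used only to describe, rank or filter peaks within this list. The annotation by HOMER gives each peak a class (promoter-TSS, exon, intron, TTS or intergenic), the gene with the nearest transcription start site (TSS) and the signed distance from the peak's centre to it, per the file headers. Promoter-TSS peaks had centres from 999 bp upstream to 817 bp downstream of the TSS. Coordinates are 1-based rn6 positions as in the annotation.

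Sequencing depth is unknown, because the peak list gives no library totals. Absence of a peak therefore means no call at this depth and threshold. It can also reflect naming, since a peak counts only for the gene whose name the annotation gives it. A nearer gene model or an unnamed model can hold a peak that lies beside another gene.

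Names were matched to a gene table of assembly GRCr8, used for names, gene order and the background alone, because its build differs from that of the peaks. Of 8094 names in the annotation, 6132 matched a current symbol, 141 an older symbol and 1821 none, so 77.5% of names matched. All 563 list entries (561 genes, 2 of them in 2 lists) had a row in the table. The background was the table's 23149 protein-coding genes, of which 2172 have LOC placeholder symbols.

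For each of 21 gene lists, the share of members with at least 1 promoter-TSS peak was computed with a 95% Clopper-Pearson interval. The lists were mitophagy and autophagy, mitochondrial dynamics and biogenesis, oxidative phosphorylation, glycolysis and lactate handling, fatty acid oxidation, hypertrophic growth with the fetal gene programme, cardiac sarcomere, calcium handling with cardiac ion channels, fibroblast and extracellular matrix, endothelial, smooth muscle and pericyte, immune cell, inflammatory signalling, autonomic signalling, lysine acylation enzymes and readers, housekeeping, brain, hepatocyte, male germ cell, skeletal muscle, and adipocyte. Each share was placed as a percentile among 10000 random lists of the same size. Random lists with the same share were counted in equal parts as lower and higher. A list was called above or below when its percentile, so counted, fell in the upper or lower 2.5%. With ties counted this way, lists under 29 genes cannot be called below at this background, and 6 of the 21 lists reach that size. Shares of peaks have 95% Wilson intervals. All intervals cover counting error only, since peaks and genes of 1 library are not replicates and PCR duplicates were not separable. No p-value was computed, because 1 library allows no test. The difference in median fold enrichment was resampled over peaks 1000 times, a step added to the planned description.

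The method was tested on simulated lists, with peak status drawn at random and independently for each of 23149 genes. The rates below hold for such independent genes and do not cover lists of related or widely active genes. Lists of 49 genes with an unchanged promoter share were called above in 1% of 200 draws, those with a share 2 times the background in 45.5%, and those with a share 4 times the background in 100%. At 25 genes these figures were 3.5%, 44.5% and 98.0%. Simulated lists of 49 genes with no promoter peak were always called below, and those of 25 or 12 genes never, an outcome that list size fixes.

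The 21 lists, the tests of the report, the rule for named genes and all alternatives except those named in the closing section as added later were fixed before the data were examined. The rule took from each list the 3 members with the strongest promoter peaks and up to 2 members, first by alphabet, with no peak. It also took the 5 strongest promoter peaks and the 5 strongest other peaks on chromosomes 1 to 20, X and Y, the 5 widest peaks, every mitophagy gene without a promoter peak, and Nppa, Nppb, Myh6, Myh7, Pink1, Bnip3, Fundc1, Ldha, Chrm2 and Chrna7. Some genes that the rule takes are not reported here. Alternatives were stricter thresholds on q and fold enrichment, merging of near peaks, windows of 1000 and 3000 bp around the TSS, any assigned peak, other backgrounds, lists without shared members, and −log10 q in place of fold enrichment. Random placement of peaks along the genome and random lists matched on gene length were planned but not run, because no genome or annotation of the peaks' build was used here. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.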

Results

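H3K18la is a histone mark made from lactate, and the series title connects it with mitophagy, the removal of damaged mitochondria, in cardiac hypertrophy. The data analysed were the peaks of 1 ChIP library from myocardium of rats with abdominal aortic constriction. Its input library had no values here, and no library labelled as from unoperated or stimulated rats was analysed, so no comparison between groups was made. The questions the list can answer are where the mark was called in the myocardium of this model and at which genes. There are no replicates, so no value below has a replicate error.

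The library gave 28706 peaks covering 14.974 Mb of rn6. Most were short and of moderate strength. Peak width had a median of 375 bp, with quartiles of 260 and 597 bp and a range of 200 to 12549 bp. The authors' fold enrichment had a median of 4.13, with quartiles of 3.62 and 4.79, and reached at least 6 in 1811 peaks (6.31%) and at least 10 in 28 peaks. The median −log10 q was 3.89.

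Peaks lay mainly in introns and between genes, and were densest just downstream of transcription start sites. Introns held 12575 peaks (43.8%, 95% Wilson interval 43.2 to 44.4%) and intergenic sequence 11803 (41.1%, 40.5 to 41.7%). Promoters held 2807 (9.78%, 9.44 to 10.1%), exons 1015 (3.54%) and transcription termination sites 479 (1.67%). Of the intron peaks, 6276 (49.9%) lay in intron 1. Within 1000 bp of a TSS there were 5569 peaks (19.4%, 18.9 to 19.9%), 2240 with the centre upstream and 3329 downstream. Of the downstream peaks, 1976 were classed as intron and 632 as exon, so the promoter class leaves out many peaks close to a TSS. The fullest 250 bp bin, from 250 to 500 bp downstream, held 1380 peaks. The share of the genome that each class takes up was not analysed here.

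**Figure D1:**
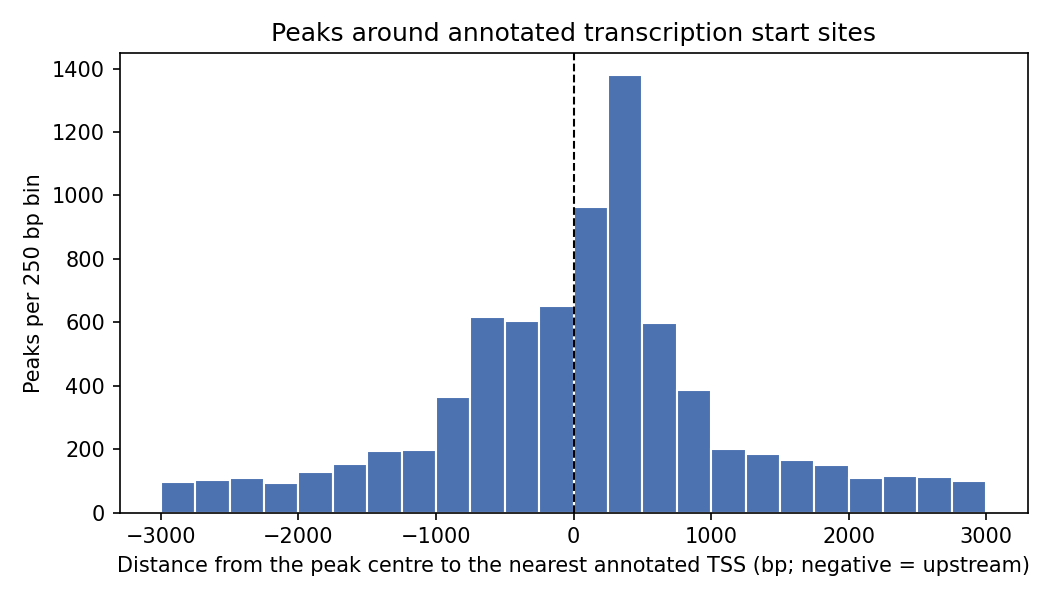
Number of peaks (y axis, peaks per 250 bp bin) by signed distance of the peak centre from the nearest annotated TSS (x axis, bp, negative upstream), for the 1 ChIP library. The bin from 250 to 500 bp downstream holds 1380 peaks, against 652 in the 250 bp just upstream of the TSS.

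Promoter peaks were about as strong as the rest. Their median fold enrichment was 4.09 (quartiles 3.45 and 4.81), against 4.14 (3.62 and 4.79) for all other peaks, a difference of -0.0466 (resampling interval -0.107 to -0.00815). By −log10 q the order turned, with medians of 4.33 at promoters and 3.89 elsewhere. The order also turned, to a difference of 0.047, among peaks of fold enrichment of at least 4.

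The strongest promoter peak was that of Ppp1r15a, a stress-induced regulator of protein phosphatase 1, at 10.7-fold (chromosome 1, 101514297 to 101515118). The next strongest belonged to the unnamed gene model AABR07044415.1 at 10.4-fold (chromosome 20, 5259101 to 5261634), to Wbp1l at 10.3-fold (chromosome 1, 266377408 to 266382584) and to Sgk1, a kinase induced by serum and glucocorticoids, at 10.3-fold (chromosome 1, 24190958 to 24191727). Rhobtb1 followed at 9.54-fold (chromosome 20, 20711948 to 20714133). Outside promoters, the strongest peak of the list lay between genes, 5.53 kb upstream of the microRNA gene Mir23a, at 13.7-fold (chromosome 19, 25310887 to 25315219). It was followed by peaks in intron 1 of Klf9 at 12.1-fold (chromosome 1, 240908327 to 240912290) and in intron 3 of Zbtb16 at 11.6-fold (chromosome 8, 53055445 to 53063023). Both genes encode zinc finger transcription factors that glucocorticoids induce. Intergenic peaks nearest to the unnamed model AABR07054619.1 (11.4-fold, chromosome 3, 164598518 to 164600675) and to Jade2 (11.3-fold, chromosome 10, 37313840 to 37315839) completed the 5.

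The widest peak, 12549 bp, was intergenic, 31.1 kb upstream of the unnamed model AABR07072667.1 (chromosome 19, 59725270 to 59737818). A peak of 11707 bp lay in intron 3 of Zbtb16 (chromosome 8, 53063209 to 53074915), next to the strong Zbtb16 peak. An intergenic peak 42.3 kb upstream of Pomgnt2 spanned 9046 bp (chromosome 8, 130655636 to 130664681). The promoter peak of Zmynd8, a chromatin reader, spanned 8959 bp (chromosome 3, 162577271 to 162586229). At Dusp1, a stress-induced MAP kinase phosphatase, a peak of 8344 bp lay at the transcription termination site (chromosome 10, 16969275 to 16977618).

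Of the 49 mitophagy and autophagy genes, 9 had a promoter peak (18.4%, 95% Clopper-Pearson interval 8.76 to 32.0%), against 9.88% of the 23149 background genes. This was percentile 96.7 among random lists, short of the upper 2.5%, so the list was not called above. A further 19 genes had a peak elsewhere, which gave 28 of 49 genes (57.1%, 42.2 to 71.2%) with any peak, against 27.1% of background genes and at percentile 100. The call thus depended on what counts as a promoter peak. With a peak centre within 1000 bp of the TSS, 20 of 49 genes (40.8%) had one, against 17.1% of the background, again at percentile 100. These shares were not particular to mitophagy. Housekeeping genes had 14 of 25 (56.0%) with any peak and 11 of 25 (44.0%) within 1000 bp. Among genes with any peak, however, 9 of 28 mitophagy genes (32.1%) had a promoter peak against 36.5% of that background, at percentile 32.4. At −log10 q of at least 5 the list was at percentile 74.5, and at fold enrichment of at least 4 at percentile 60.9. Most of the promoter peaks were modest, with a median fold enrichment of 3.61 over the 9 genes, and 3 of the 9 genes kept a promoter peak at −log10 q of at least 5.

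The strongest mitophagy promoter peaks were those of Vdac1, the main channel of the outer mitochondrial membrane, of Bnip3, a mitophagy receptor of that membrane, and of Sqstm1, the autophagy adaptor p62. Vdac1 had 5.23-fold enrichment at chromosome 10, 37724385 to 37725452. Bnip3 had 5.11-fold at chromosome 1, 211265968 to 211266470, and a stronger intergenic peak of 6.33-fold 5.99 kb upstream (211270881 to 211271671). Sqstm1 had 4.95-fold at chromosome 10, 35715857 to 35717480. Among members without a promoter peak, the ubiquitin-like autophagosome proteins Map1lc3a and Map1lc3b had peaks of 7.32-fold (392 bp downstream of the TSS, intron 1, chromosome 3, 150800874 to 150802488) and 6.76-fold (1502 bp upstream, chromosome 19, 53627759 to 53628795). The adaptor Tax1bp1 had an intergenic peak of 6.85-fold, 12.2 kb upstream. Fundc1, a mitophagy receptor encoded on the X chromosome, had a single peak of 5.93-fold in intron 1, 725 bp downstream of the TSS (chromosome X, 5550012 to 5550277).

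The other 15 mitophagy members with peaks outside promoters reached from 2.95-fold at Rb1cc1 to 5.92-fold at Csnk2a1. They were Atg13, Atg7, Csnk2a1, Gabarapl1, Marchf5, Mul1, Nipsnap2, Optn, Rab7a, Rb1cc1, Tbk1, Tfeb, Ulk1, Wdr45 and Wipi1. No peak carried the name of 21 members, among them Pink1, a kinase that marks damaged mitochondria. Also among them were Atg5, Atg9a, Bcl2l13, Becn1, Calcoco2, Fkbp8, Lamp1, Lamp2, Nbr1, Nipsnap1, Pgam5, Phb2, Tfe3, Tomm20, Tomm7, Usp15, Usp30, Usp8 and Wipi2. Lamp2 and Tfe3 are X-linked, and the X chromosome had few peaks.

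Genes of energy metabolism often carried promoter peaks, as housekeeping genes also did (9 of 25, 36.0%). Fatty acid oxidation had them at 13 of 28 genes (46.4%, 27.5 to 66.1%, percentile 100), led by Ech1 at 6.29-fold, Etfb at 6.15-fold and Hadha at 5.68-fold. Ech1 and Hadha encode enzymes of fatty acid β-oxidation and Etfb a subunit of the flavoprotein that takes up its electrons. Glycolysis and lactate handling had them at 15 of 35 genes (42.9%, 26.3 to 60.6%, percentile 100), led by the enolase Eno1 at 6.17-fold, the mitochondrial pyruvate carrier subunit Mpc1 at 5.33-fold and the aldolase Aldoa at 4.92-fold. Ldha, which makes lactate from pyruvate, had a promoter peak of 4.60-fold (chromosome 1, 102899456 to 102899843). Oxidative phosphorylation had promoter peaks at 10 of 38 genes (26.3%, 13.4 to 43.1%, percentile 99.8), with Atp5f1c of the ATP synthase at 8.10-fold (chromosome 17, 72209277 to 72209870), cytochrome c (Cycs) at 5.03-fold and Sdha at 4.55-fold. Most of these peaks were modest, with a median of 3.73-fold over the 10 genes. The list was not called at −log10 q of at least 5 (percentile 95.15) or at fold enrichment of at least 4 (percentile 89.9). Against genes with any peak, glycolysis and lactate handling stayed above (percentile 99.4). Fatty acid oxidation (97.3) and oxidative phosphorylation (84.7) were not called there. No peak carried the name of Cd36, Cpt1b, Aldoc, Eno3, Atp5f1b or Atp5pb. Mitochondrial dynamics and biogenesis was not called, with 3 of 22 genes (13.6%, 2.91 to 34.9%, percentile 73.2). These 3 were the nuclear receptor Esrra at 4.88-fold, the fusion protein Mfn2 at 3.62-fold and Tfb1m at 3.11-fold, while the fission genes Dnm1l and Fis1 had no peak.

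By promoter-class peaks, hypertrophy and sarcomere genes were also called above, and calcium handling genes were not. Hypertrophic growth and the fetal gene programme had promoter peaks at 9 of 38 genes (23.7%, 11.4 to 40.2%, percentile 99.4), led by the calcium-dependent kinase Camk2d at 5.52-fold, the X-linked Fhl1 at 5.41-fold and the kinase Gsk3b at 5.06-fold. The sarcomere list had them at 9 of 29 genes (31.0%, 15.3 to 50.8%), led by desmin (Des) at 6.54-fold, Nexn at 5.24-fold and Myoz2 at 5.004-fold. Neither list was called at −log10 q of at least 5 (percentile 85.3 for hypertrophic growth, 47.6 for sarcomere). Nor was either called against genes with any peak (37.5 and 66.4). At fold enrichment of at least 4, hypertrophic growth was not called (percentile 96.6) and sarcomere was (99.8). Calcium handling and ion channels had promoter peaks at 5 of 26 genes (19.2%, 6.55 to 39.4%, percentile 92.8), among which Kcnd3 had 4.07-fold and Kcnq1 3.66-fold. This contrast depended on the promoter class. With the 1000 bp window, calcium handling had 9 of 26 genes (34.6%, percentile 98.5) and was called above. Hypertrophic growth had 12 of 38 (31.6%, percentile 98.5) with that window. Calcium handling was also called above with the 3000 bp window (percentile 99.05). With any peak counted, calcium handling reached 16 of 26 genes (61.5%), percentile 99.995, and was called above. Cacna2d1 and Gja5 had no peak.

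Of the classical hypertrophy markers, Myh7, the β-myosin heavy chain, had a promoter peak of 4.11-fold (chromosome 15, 33656746 to 33656968) and its strongest peak, 5.38-fold, 9.33 kb upstream (33664961 to 33665886). No peak carried the names of the natriuretic peptide genes Nppa and Nppb, of the α-myosin heavy chain Myh6, of the atrial light chain Myl7, of skeletal α-actin Acta1 or of the angiotensin receptor Agtr1a. At Myh6, the neighbour of Myh7, the absence of the name can reflect naming. Downstream of the Myh7 promoter peak stood 2 peaks assigned to the unnamed model AC130940.1 (chromosome 15, 33631123 to 33631322 and 33633552 to 33633757, 3.66-fold and 3.70-fold). A peak of class intron assigned to the microRNA gene Mir208b (33636022 to 33636221, 3.38-fold) lay on the same side. Whether any of these peaks lies in Myh6 rather than in Myh7 cannot be read from the assigned names, so they do not settle the question for Myh6.

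Among lists of cell types, endothelial genes had the highest share. Promoter peaks stood at 11 of 20 endothelial genes (55.0%, 31.5 to 76.9%, percentile 100) and any peak at 18 of 20, with the transcription factors Sox17 at 6.99-fold and Erg at 5.38-fold and the receptor Tie1 at 5.35-fold. Pecam1 and Emcn had no peak. Fibroblast and matrix genes were not called, with 5 of 27 (18.5%, 6.30 to 38.1%, percentile 91.5), led by Tgfbr1 at 5.41-fold, Sparc at 4.75-fold and Vim at 3.93-fold, and Col1a1 and Col1a2 had no peak. With any peak counted, they reached 12 of 27 (44.4%, percentile 97.7) and were called above. Smooth muscle and pericyte genes had 2 of 13 (15.4%, percentile 74.9), Abcc9 at 5.18-fold and Cspg4 at 4.09-fold, with no peak at Cnn1 or Kcnj8, and 7 of 13 (53.8%, percentile 97.8, called above) with any peak counted. None of 33 immune cell genes had a promoter peak (0%, interval 0 to 10.6%, percentile 1.66), the only list called below at promoters. With any peak counted they had 5 of 33 (15.2%, percentile 5.81) and were not called, and Adgre1 and C1qa had no peak of any class.

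Inflammatory signalling genes, unlike immune cell genes, were called above, with promoter peaks at 7 of 24 (29.2%, 12.6 to 51.1%, percentile 99.5). The interleukin receptor gene Il1r1 had 7.77-fold (chromosome 9, 46996454 to 46997679), the NF-κB subunit Rela 5.91-fold and the adaptor Myd88 5.52-fold, and the median over the 7 genes was 5.23-fold. No peak of any class carried the name of 10 of the 24 genes. These were Hmgb1, Icam1 and, outside the rule for named genes, Il1b, Il18, Il6, Nlrp3, Tlr2, Tlr4, Tnf and Vcam1. The difference between the immune and inflammatory lists was not itself tested. Housekeeping genes had promoter peaks at 9 of 25 (36.0%, 18.0 to 57.5%), with β-actin (Actb) at 9.37-fold, Eef1a1 at 6.29-fold and Ywhaz at 5.25-fold, and no peak at Chmp2a or Emc7.

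Autonomic signalling genes, which include the receptors through which the vagus acts on the heart, had a promoter peak at 1 of 26 (3.85%, 0.0973 to 19.6%, percentile 16.7). With any peak counted they had 6 of 26 (23.1%, percentile 33.4) and were not called. With the 3000 bp window they had 1 of 26 (percentile 1.58) and were called below. The main cardiac muscarinic receptor Chrm2 had its strongest peak, 7.08-fold, 43.7 kb downstream of the TSS and between genes (chromosome 4, 64132415 to 64132768), and the nicotinic receptor Chrna7 had none, nor did Ache or Adra1b. Enzymes and readers of lysine acylation had promoter peaks at 2 of 23 genes (8.70%, percentile 46.1), among them the acetyltransferase Kat7 at 3.93-fold. Aars1 and Aars2 had no peak.

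Of the lists of other tissues, none was called above at promoters, and none was long enough to be called below. Gad1 at 2.95-fold was the 1 of 25 brain genes (percentile 17.4), Casq1 at 4.03-fold the 1 of 26 skeletal muscle genes (percentile 16.4) and Pparg at 3.94-fold the 1 of 12 adipocyte genes (8.33%, percentile 47.4). With any peak counted, adipocyte genes had 6 of 12 (percentile 94.9), brain genes 3 of 25 (12.0%, percentile 4.08) and male germ cell genes 1 of 20 (percentile 0.84, called below). Hepatocyte genes had 0 of 24 (interval 0 to 14.2%, percentile 3.96) and male germ cell genes 0 of 20 (0 to 16.8%, percentile 6.31). Genes with no peak of any class included Camk2a, Dcx, Alb, Ahsg, Acr, Dazl, Atp2a1, Cacna1s, Cebpa and Cidec.

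**Figure D2:**
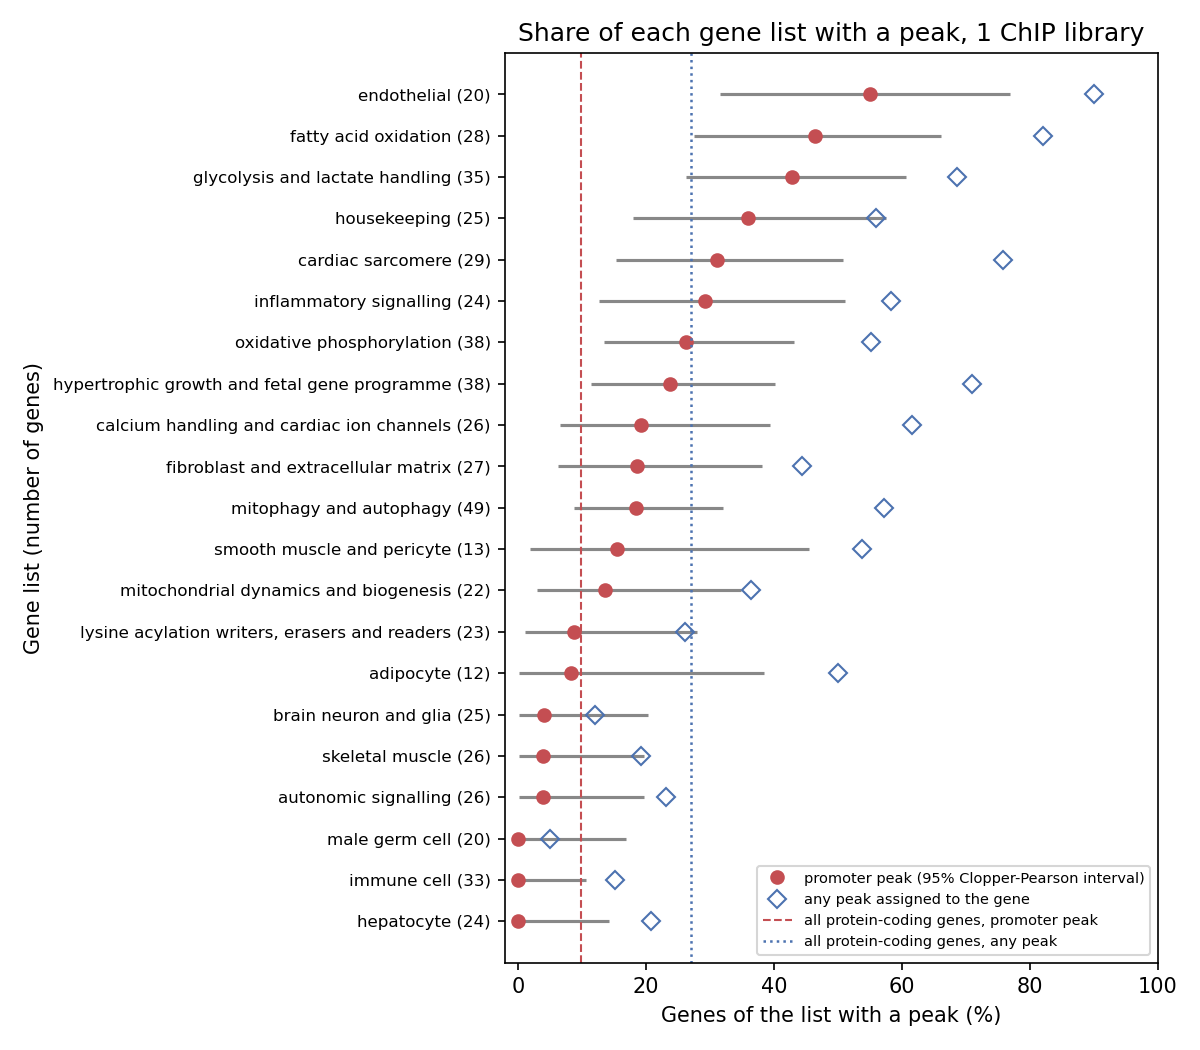
Percent of the genes of each list (x axis) with a promoter peak (red points, bars for 95% Clopper-Pearson intervals) or any assigned peak (blue diamonds), for the 21 lists (y axis, number of genes in brackets) in the 1 ChIP library. Dashed and dotted lines mark the 9.88% and 27.1% of all background genes, and the endothelial list lies highest, at 55.0% for promoter peaks and 18 of 20 genes for any peak.

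In all, 8 lists were called above and 1 below, where chance would give about 0.525 lists in the upper tail and, over the 6 lists long enough to be called below, about 0.15 in the lower. These chance figures hold for lists drawn at random from all background genes. That background was not limited to genes active in myocardium or to names the annotation uses, and the housekeeping list was itself called above. Against a background of genes that carry any peak, the calls above fell to 3 lists (glycolysis and lactate handling, endothelial, housekeeping). At −log10 q of at least 5, 5 lists stayed above (glycolysis and lactate handling, fatty acid oxidation, endothelial, inflammatory signalling, housekeeping). Under both settings the immune cell list could not have been called below with 0 members. With any assigned peak counted, 12 lists were above, which adds mitophagy and autophagy, calcium handling, fibroblast and matrix, and smooth muscle and pericyte genes, and the male germ cell list was the 1 below.

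The X chromosome had far fewer peaks than any autosome. It held 234 peaks, or 14.6 per 10 Mb up to its last peak, against 75.5 on chromosome 2, the sparsest autosome, and 181 on chromosome 10, the densest, with an autosome median of 112. Its peaks were stronger, with a median fold enrichment of 4.51 against 4.07 to 4.23 over the 20 autosomes, and 17.5% of them lay in promoters against 7.32 to 12.3%. The Y chromosome had 2 peaks, and 46 peaks lay on 29 unplaced or other sequences.

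**Figure D3:**
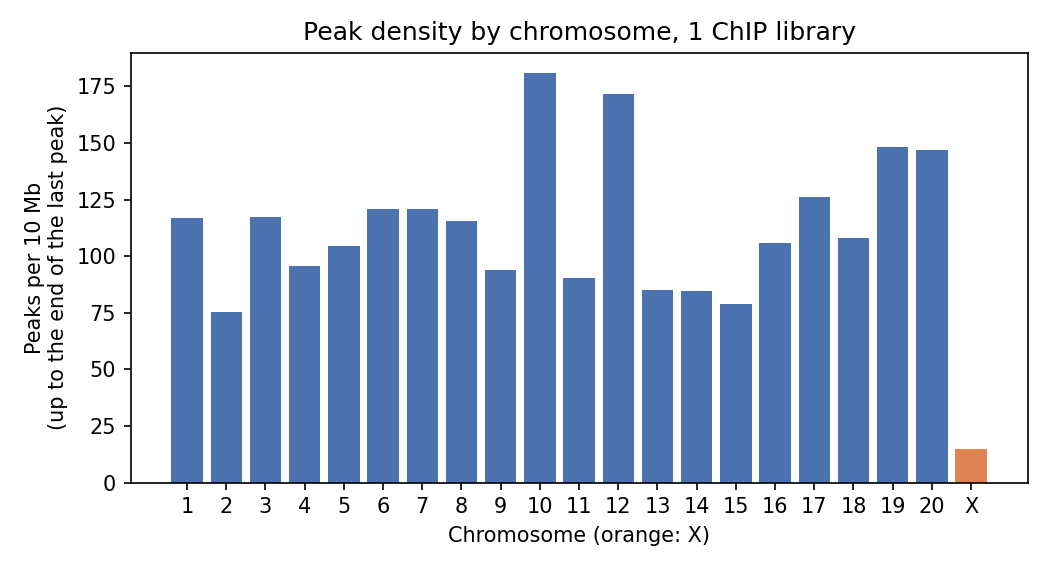
Peaks per 10 Mb up to the end of the last peak (y axis) on each autosome and the X chromosome (x axis, X in orange), for the 1 ChIP library. The X has 14.6 peaks per 10 Mb, and the autosomes range from 75.5 to 181.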

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

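Alternatives were planned except the background without LOC symbols, which was chosen after seeing the data and left the calls of all 21 lists on the same side. Stricter thresholds leave fewer peaks by construction, and the cause of the other changes was not tested. The number of peaks was 9179 at −log10 q of at least 5, 1309 at 10 or more, 15939 at fold enrichment of at least 4 and 18941 after merging within 1000 bp. The promoter share in that order of thresholds was 12.4%, 14.7% and 9.34%, and 19.4% and 27.1% with windows of 1000 and 3000 bp. The difference in median fold enrichment, promoter minus other, was -0.194 and -0.229 at the 2 q thresholds. It reversed to 0.0471 at fold enrichment of at least 4, to 0.011 with the 1000 bp window and to 0.44 in −log10 q. Lists above numbered 5 and 3 at the q thresholds and 3 against genes with any peak, and 6 at the fold threshold, 9 and 10 with the windows and 12 with any assigned peak. Lists below numbered 0 at either q threshold, at the fold threshold and against genes with any peak, 2 with the 1000 bp window and 4 with the 3000 bp window. No list could have been called below at these 3 thresholds, so those counts of 0 say nothing about stability. Against genes with any peak 13 of 21 lists could have been, but not the immune list. The mitophagy share was 6.12% at −log10 q of at least 5, 0% at 10 or more, 6.12% at the fold threshold, 40.8% and 44.9% with the windows and 57.1% for any peak. Of the 46 genes with promoter peaks that the rule took from the lists or by name, 32, 11 and 39 still had one at the q thresholds and the fold threshold. The housekeeping call held in 9 of 9 alternatives, those of glycolysis and lactate handling, fatty acid oxidation and endothelial genes in 8 of 9, inflammatory signalling in 7, sarcomere in 6, oxidative phosphorylation and hypertrophic growth in 5. The immune cell call held in 4 of the 5 alternatives that allowed it, and not with any assigned peak. Leaving out shared members altered only the hypertrophic growth and sarcomere lists. For every other list, the immune cell list included, that alternative is counted in these figures but repeats the main setting and is no separate check. Random placement of peaks and lists matched on gene length were not run, for lack of a matching genome here. No paired analysis was possible because 1 library holds all values. Unknown depth limits every statement of absence.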

Other observations

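The division of genes by their strongest peak, its matching on peak number, the glucocorticoid tests and the fold enrichment test on the X chromosome were chosen after the data were seen; the immediate-early list and the test of X-linked genes were written down before their values were seen. Matching on peak number pooled genes with 8 or more assigned peaks, and a closer match, added last, drew each gene from at least 50 genes with the same or the nearest peak numbers.

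Endothelial genes also carried strong peaks when peaks of every class were counted. Of the 20 genes of the list, 9 (45.0%, 95% Clopper-Pearson interval 23.1 to 68.5%) had a peak of at least 6.48-fold, which marks the top 10% of genes with a peak, against 2.78% of all background genes. The count was at percentile 100 of random lists and at percentile 99.6 of random genes matched on peak number, which gave 4.09 on average. With 6 of the 20 genes above 8 peaks, the closer match gave 4.56 on average and percentile 99.3. The 9 genes were the adhesion molecule Esam (9.63-fold, intron, 1.04 kb downstream of the TSS), the receptors Kdr (7.61-fold, 70.6 kb downstream), Eng (7.27-fold) and Tek (6.90-fold), Egfl7 (7.002-fold), Sox17 (6.99-fold), Sox18 (6.73-fold), Fli1 (6.56-fold) and the nitric oxide synthase Nos3 (6.51-fold). Of these peaks, that of Sox17 is its promoter peak given above, and the others lie outside the promoter class. Hypertrophic growth genes had 5 of 38 in this top 10% (13.2%, percentile 99.8), Xirp1 at 8.33-fold, Gdf15 at 7.78-fold, Mef2d at 7.34-fold, Nfatc3 at 6.76-fold and Mef2c at 6.68-fold. Genes matched on peak number gave 4.30 on average, which put this count at percentile 66.0, and the closer match at 74.3. Inflammatory signalling had 3 of 24 (percentile 98.5, 86.35 when matched, 82.7 with the closer match), with Nfkbia, the inhibitor of NF-κB, at 8.64-fold, 18.8 kb downstream of its TSS. Housekeeping genes had 3 of 25 (percentile 98.4, matched 97.2, closer match 97.85) and calcium handling genes 3 of 26 (percentile 98.25, matched 71.9, closer match 67.0).

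Strong peaks at Klf9, Zbtb16, Sgk1 and Dusp1 led to the hypothesis that glucocorticoid exposure before tissue collection may mark this myocardium. Of 21 other textbook response genes, 4 had a peak in the top 10% (Zfp36 at 9.85-fold, Tgm2 at 7.67-fold, Foxo3 at 7.27-fold, Per2 at 7.21-fold), percentile 99.9 of random lists, but only percentile 61.0 of genes matched on peak number (68.5 with the closer match), which gave 3.59 on average, so peak number could account for the count. That list was shortened after a first result: with Fkbp5, Per1, Tsc22d3 and Hif3a, whose peaks had been seen, it had 7 of 25 genes at percentile 90.6 of the matched draws (93.2 with the closer match). Immediate-early and heat shock genes had 7 of 25 (percentile 100, 99.1 when matched and 99.2 with the closer match), led by Nr4a2 at 8.87-fold and Junb at 8.07-fold, but no peak carried the names of 7 others, the highly inducible Egr1, Egr2, Egr3, Atf3, Hspa1a, Hspa1b and Hsph1, so a general stress response during tissue collection may account for part of the list and stays open. Peak number comes from the same peak list and could itself rise with the mark, so the match cannot decide between the 2. Glucocorticoid exposure thus cannot be told apart from peak-rich loci in 1 library. An effect of aortic constriction stays open and untested, since no unoperated animal was analysed.

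The X chromosome's low peak density, 0.131 times the autosome median, is not accounted for by fewer genes: 89 of its 936 protein-coding genes (9.51%, 7.71 to 11.6%) carried a peak, against 20.3% on chromosome 19, the lowest autosome. A candidate explanation is lower coverage of the single X of male rats, where a peak needs a higher fold enrichment to pass the same q. The weakest X peaks were stronger, with a 5th percentile of 3.22-fold (resampling interval 3.10 to 3.38) against 2.79 to 2.95 on the autosomes. Among peaks of at least 6-fold, the density was 0.254 times the autosome median, with 28 X peaks. This fell short of the minimum ratio set for the coverage explanation after the data were seen, so that part of its prediction was not met. How far lower coverage would close the gap was not measured. Without coverage values, coverage and a lower level of the mark on the X cannot be told apart, and no biological explanation was tested.

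In 4 peaks, singled out after their values were seen, a very small q went with a low fold enrichment. The extreme was an intergenic peak on chromosome 13 (33504657 to 33504880) with 1.74-fold enrichment and a −log10 q of 433. A pair on chromosome 1 (180808652 to 180808865 and 180806689 to 180806938) had 1.58-fold and 1.70-fold with −log10 q of 224 and 209, and a promoter peak of an unnamed model on chromosome 4 (77446543 to 77446843) had 2.28-fold with 36.5. The other 231 peaks under 2.5-fold reached at most 14.6.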
